A study of Rattus norvegicus with 12 samples.

How the data were processed

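Gene expression was measured by bulk RNA sequencing in H9C2 cells, an established line of rat heart-derived myoblasts that carries features of both cardiac and skeletal muscle. Per the labels' protocols, polyadenylated RNA was enriched with oligo(dT) beads, fragmented, reverse transcribed and amplified by PCR. There were 12 libraries in 3 groups of 4. Control cells stayed under normal oxygen and received no lentiviral vector. The H/R group received an empty lentiviral vector and went through hypoxia (1% oxygen for 8 h) and reoxygenation (2 h). The H/R + LITAF group received a lentiviral vector that overexpresses LITAF, a lysosome- and endosome-associated membrane protein first described as an LPS-induced TNF factor, before the same hypoxia and reoxygenation. Groups and replicate numbers were taken from the sample titles. The labels call the replicates biological and place all libraries in 1 batch, and they do not say whether each came from a separate culture, so p-values measure the spread between these libraries.

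The values used were the deposited estimated read counts per gene. Per the file headers, the authors deposited these expected counts as raw read counts at the gene level with Ensembl rat gene IDs, not normalized before deposit. They were not all whole numbers, so they were treated as estimated counts. Per the submitters' processing notes, DESeq2 and edgeR were used, with no role or version stated. The aligner, the quantifier, the genome build and the annotation release are not given in the sources used here, and whether counting used strand is not stated either, so overlapping genes, close paralogs and pseudogenes are uncertain. The table had 16204 gene rows, all marked protein-coding. The share of values that were not whole numbers was 2.79 to 3.34% in the control columns and 11.1 to 12.2% in the columns of the H/R groups.

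Of these rows, 258 shared a gene ID with another row, covering 128 IDs. For 56 of these IDs the rows were identical and 1 was kept. For the other 72 IDs the rows differed, and these genes were left out. All 72 differed in the control columns and were identical in the 8 columns of the H/R groups. This left 16002 gene IDs. Total counts per library ran from 16.9 to 20.7 M, so depth differed little between libraries. The precision of a gene's value is limited by counting error in genes with few reads, and by the spread between libraries above that. Decimal values were rounded to whole numbers before any count test.

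Genes with low counts were removed with edgeR's filterByExpr by group with default settings, which left 11398 genes. Libraries were scaled by TMM. All 12 libraries entered 1 fit with a mean per group, and differences were tested with edgeR's quasi-likelihood F-test (glmQLFit with robust estimation, edgeR 4.0.16, limma 3.58.1, R 4.3.3), two-sided. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The common biological coefficient of variation was 14.5%. Levels are CPM (counts per M reads) after TMM scaling, as mean ± SD over the 4 libraries of a group, and fold changes are log2 ± SE from the fit. The standard error was computed as the size of the log2 fold change divided by the square root of F. On simulated counts for H/R + LITAF against H/R, with 11249 genes tested, the test recovered 66 of 66 genes changed 4-fold, 58 of 67 changed 2-fold (86.6%) and 37 of 67 changed 1.5-fold (55.2%). False calls made up 2.84% of its calls. The simulated libraries were independent, without the axis within the LITAF group or the pairing of control and H/R libraries described below. These rates may therefore not hold for the real libraries.

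Each pair of groups was compared. Because the control cells received neither the vector nor H/R, a comparison against control cannot separate the vector from H/R. For pathways, complexes and markers of cell types, 29 gene lists were fixed before the data were examined, and 493 of their 521 entries were found in the table. The 25 lists with at least 5 measured genes were tested with limma's camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and p-values were adjusted over the lists. Camera was repeated with a correlation estimated per list, and fry was run as well. The fry p tests whether a list's genes move, on balance, in 1 direction, and compares them with no other genes. List members are counted by the gene test over all genes and again adjusted over the list alone.

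Named genes followed a rule fixed before the data were examined. They were Litaf, the 8 largest rises and 8 largest falls of each of the first 2 comparisons, up to 4 members per called list with the smallest p, 3 rises and 3 falls of the third comparison, and 5 genes with opposite and 3 with the same sign in both. The rises and falls had an adjusted p under 0.05, a mean log2 CPM of at least 2, CPM that did not overlap between the groups, and a symbol that is not a placeholder. A few genes that this rule chose are not reported here, and they stay in the fits and in the list counts. Other members of the lists are named with their values. Genes named outside this rule are said to be so.

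The labels give the groups the same replicate numbers, so it was checked whether libraries with the same number deviate together from their group means. Between control and H/R the correlations across genes were 0.40, 0.30, 0.44 and 0.57 for numbers 1 to 4, and each library correlated best with its own number. The pairing therefore comes from the values and not from the labels. Between H/R and H/R + LITAF, and between control and H/R + LITAF, not every pair was above 0.1, so these groups were treated as unpaired. The main fit did not use the pairing of control and H/R either. With a block for the replicate number, H/R against control gave 7564 calls, against 7248 in the main fit.

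Alternatives were other scalings and filters, fits of the 2 groups alone, a block for the replicate number, each library left out in turn, DESeq2 1.42.0, limma voom, stricter thresholds and other list tests. Further ones were added after seeing the data. Other splits of 8 libraries were fitted in the same way. Gene lengths, used for 1 test, came by symbol from a RefSeq table of the assembly GRCr8. They are spans of the gene with its introns. No coordinates are given because the build of the counts is not stated. Exact and permutation tests and figures were made with Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9.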

Results

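RNA was sequenced from H9C2 cells in 3 groups of 4 libraries each. The groups were cells under normal oxygen (control), cells with an empty lentiviral vector after hypoxia and reoxygenation (H/R group), and cells with a LITAF vector after the same hypoxia and reoxygenation (LITAF group). Total counts were 19.2 to 20.7 M reads in the control group, 16.9 to 18.1 M in the H/R group and 17.2 to 18.4 M in the LITAF group. Genes with a count above 0 numbered 12531 to 12879 in the control libraries, 13313 to 13477 in the H/R libraries and 13430 to 13743 in the LITAF libraries. The control libraries thus had the most reads and the fewest genes detected. The cause of this was not tested. The deposited estimated counts were scaled by TMM, and 11398 genes were tested with edgeR's quasi-likelihood test. The series asks how LITAF overexpression changes gene expression in cells exposed to H/R.

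The comparison of the LITAF group with the H/R group addresses that question, since both groups had a vector and the same H/R. Litaf itself (ENSRNOG00000002520) was measured at 2340 ± 326 CPM in the LITAF group and 585 ± 30.0 CPM in the H/R group (SD, n = 4 each). This is a 4-fold rise, log2 2.00 ± 0.10, adjusted p = 1.38e-08 by edgeR's quasi-likelihood test, and it was higher in 4 of 4 libraries. The counts do not show how many of these Litaf reads come from the vector and how many from the cells' own gene. Immediate early genes, transcription factors and regulators switched on within minutes of a stimulus, rose together, with Egr1 up 3.94-fold and Fos up 2.72-fold. Inflammatory genes also rose, among them the NF-kB feedback inhibitor Tnfaip3 (3.90-fold) and the chemokines Ccl2 (4.18-fold) and Cxcl1 (3.62-fold). The interleukin gene Il18 rose 5.36-fold and Pycard, which codes for an adaptor of the inflammasome, 3.83-fold. Casp8, the initiator caspase of death receptor signalling, went from 9.08 ± 0.953 to 36.2 ± 1.44 CPM (SD, n = 4), log2 1.99 ± 0.11.

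**Figure D1:**
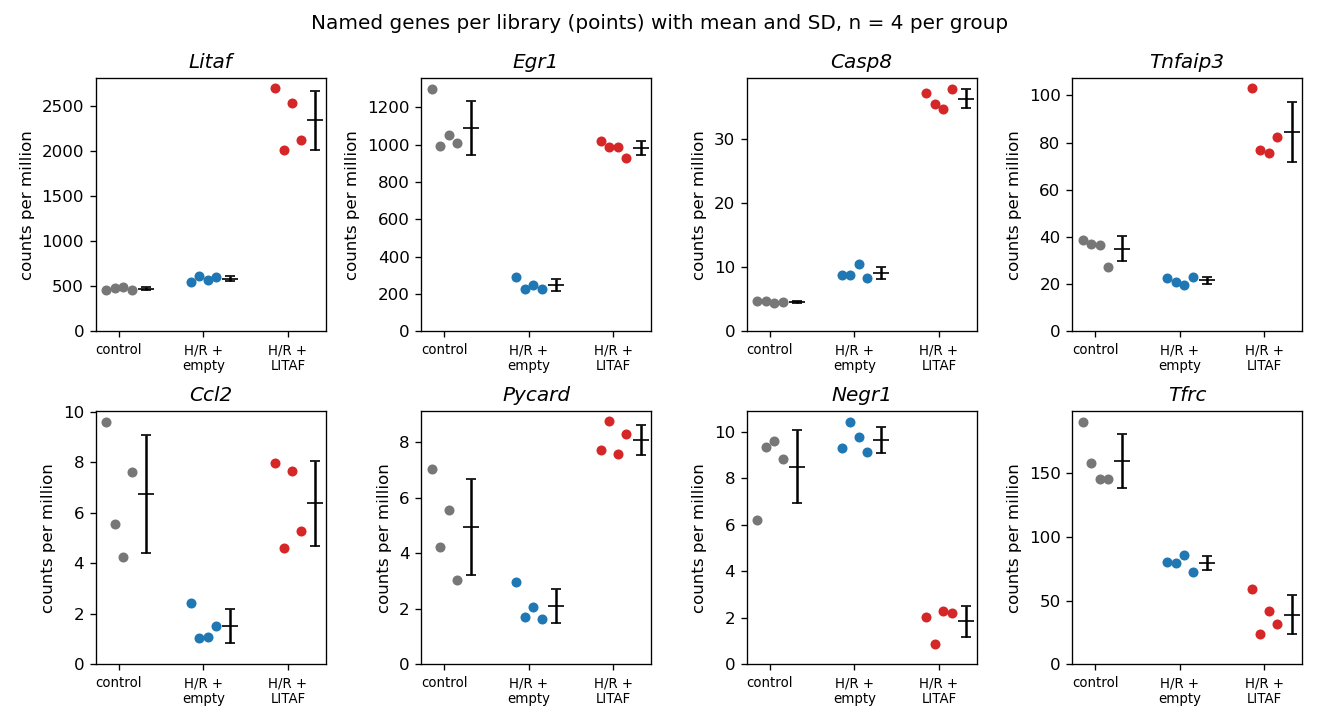
CPM after TMM scaling of 8 genes in each library, by group (control, H/R + empty vector, H/R + LITAF vector); points are libraries, and the black mark and bar are the mean and SD of the 4 libraries. Litaf lay at 2340 ± 326 CPM in the LITAF group against 585 ± 30.0 in the H/R group, and Egr1 fell from 1090 ± 143 in control to 249 ± 30.7 in the H/R group and stood at 980 ± 37.4 in the LITAF group.

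Of the 18 measured immediate early genes, 15 rose, none fell and 3 did not pass the test; adjusted over the list alone, 16 rose. Egr1 rose from 249 ± 30.7 to 980 ± 37.4 CPM (log2 1.98 ± 0.11), Junb by log2 1.18 ± 0.11 and Fosb by log2 1.10 ± 0.10. Klf2, Klf4 and Klf6 did not pass, at log2 0.21, 0.29 and 0.40. The camera test gave this list an adjusted p of 1.62e-22, and it held at an adjusted p = 0.000765 with an estimated correlation. It also held with an estimated correlation in the fit of these 2 groups alone, at adjusted p = 0.0329, and no other list did.

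In the NF-kB and inflammation list, 7 of 19 measured genes rose and none fell; adjusted over the list alone, 9 rose. Tnfaip3 rose from 21.6 to 84.4 CPM and Ccl2 from 1.51 ± 0.662 to 6.37 ± 1.68 CPM. Lif, a cytokine of the interleukin 6 family, rose 3.04-fold, while Il6 (log2 0.30 ± 0.19) and Icam1 (log2 -0.07 ± 0.13) did not pass. Tnf itself was not among the genes tested. The camera adjusted p was 1.98e-07 (adjusted p = 0.0109 with an estimated correlation). In the pyroptosis and necroptosis list, 4 of 8 rose by the test over all genes and 4 when adjusted over the list alone. These were Pycard (log2 1.94 ± 0.24), the sensor Nlrp3 (1.28 ± 0.19), the pore-forming Gsdmd (0.79 ± 0.12) and Il18 (2.42 ± 0.50). The necroptosis genes Ripk1, Ripk3 and Mlkl stood at log2 0.00, 0.00 and 0.21 and did not pass, nor did the inflammatory caspase gene Casp4 (log2 0.13 ± 0.15). The camera adjusted p was 0.000171 (adjusted p = 0.0144 with an estimated correlation). Il18 did not pass without the low-count filter, and the H/R libraries differed in it, at 7.19, 1.77, 3.47 and 2.24 CPM against 18.7 to 21.8 CPM in the LITAF group.

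Skeletal muscle markers rose in 7 of 13 measured genes and fell in none; adjusted over the list alone, 8 rose. The troponin gene Tnni1 (log2 2.92 ± 0.45) and the actin gene Actc1 (log2 2.79 ± 0.39) rose most, both from under 1 CPM. The myosin genes Myl11 and Myh3 rose 5.05-fold (3.02 ± 0.875 to 15.3 ± 4.90 CPM) and 4.44-fold (4.95 ± 1.42 to 22.0 ± 7.16 CPM), the myosin gene Myl4 did not pass (log2 0.32 ± 0.19), and Mybph, a myosin-binding protein outside the list, rose 4.05-fold. The regulators Myod1 (log2 0.18 ± 0.17) and Myog (log2 1.19 ± 0.46) did not pass. The camera adjusted p was 3.07e-08 (adjusted p = 0.0423 with an estimated correlation). Among extracellular matrix and TGF-beta genes, 5 of 17 rose, 9 when adjusted over the list alone, and none fell. Ccn1 rose 3.03-fold (292 ± 7.30 to 884 ± 92.5 CPM), Col3a1 1.52-fold and Ccn2 1.46-fold. The camera call (adjusted p = 5.02e-06) was lost at adjusted p = 0.0873 with an estimated correlation. Fmod, which codes for the collagen-binding fibromodulin and is not in the list, rose 5.31-fold, from 2.62 ± 0.437 to 14.0 ± 1.15 CPM.

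Among HIF target genes, which respond to low oxygen, 2 of 21 rose (5 adjusted over the list alone), Adm 2.56-fold and Bhlhe40 1.57-fold, while Vegfa stood at log2 -0.01 ± 0.11. The camera adjusted p was 0.00115 (adjusted p = 0.0199 with an estimated correlation). Of the NRF2 antioxidant genes, 3 of 18 rose (5 adjusted over the list alone), Srxn1 3.44-fold, Hmox1 1.45-fold and Ftl1 1.35-fold. Of the ferroptosis genes, 4 of 16 rose and 1 fell (5 and 1 adjusted over the list alone), and 2 of the 4, Hmox1 and Ftl1, belong to both lists. The gene that fell was Tfrc, the transferrin receptor for iron uptake, from 79.3 ± 5.46 to 39.1 ± 15.3 CPM. Their camera calls (adjusted p = 0.00206 and 0.0231) were lost at adjusted p = 0.0634 and 0.0842 with an estimated correlation. Of 24 lysosome genes 1 rose, Grn (1.34-fold), and 2 rose adjusted over the list alone. Of 24 cytosolic ribosomal protein genes none passed, by either adjustment. These 2 lists had medians of log2 0.15 and 0.18, and their camera calls (adjusted p = 0.00115 and 0.00109) were lost at adjusted p = 0.108 and 0.477 with an estimated correlation.

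The mitosis and DNA replication lists shifted down as a whole, with medians of log2 -0.30 and -0.22. None of the 19 mitosis genes passed singly, and 1 of 16 replication genes fell, the cyclin gene Ccne2 (log2 -0.83 ± 0.22); adjusted over the list alone, 0 and 4 fell. The camera adjusted p was 3.87e-05 for mitosis genes (adjusted p = 0.0459 with an estimated correlation) and 0.000198 for replication genes (adjusted p = 0.0144 with an estimated correlation). The largest fall was in Negr1, a neuronal adhesion molecule, from 9.65 ± 0.551 to 1.86 ± 0.663 CPM, log2 -2.38 ± 0.22. The homeobox gene Prrx2 was 2.75-fold lower, the protease inhibitor gene Serpinb7 2.36-fold, the glycoprotein gene Cd200 2.20-fold and the forkhead gene Foxc2 2.05-fold. Zfp239l1 and Zfp748-ps1 were 2.65-fold and 2.05-fold lower; both have close paralogs, and the second is named as a pseudogene, so their counts are uncertain. The other 13 lists did not pass the camera test.

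In all, 425 genes rose and 131 fell, 556 of 11398, with 109 and 23 of them by at least 2-fold. CPM of the groups did not overlap for 2150 genes (18.9%), against 2.86% from chance with 4 libraries per group. Rises made up 76.4% of the calls with TMM, 61.0% with library totals alone and 66.5% with upper-quartile scaling; without LITAF library 1, 692 genes rose and 593 fell. The libraries of the LITAF group were spread along 1 axis that held 52.3% of the variance within the 2 groups; library 1 scored -0.68, library 3 -0.20, library 4 0.25 and library 2 0.63, and the H/R libraries lay between -0.13 and 0.12. List members were also counted with each library of the 2 groups left out, a count chosen after seeing the data. Over these 8 fits 10 to 15 immediate early genes rose (fewest without H/R library 3), 5 to 6 NF-kB, 3 to 4 pyroptosis, 6 to 7 skeletal muscle and 2 to 3 HIF genes. Of matrix genes 9 rose without LITAF library 1 and 2 to 3 in the other fits, of ferroptosis genes 0 to 4, of NRF2 genes 1 to 3, of lysosome genes 0 to 3 and of unfolded protein response genes 0 to 2. Of mitosis genes 4 fell without LITAF library 1 and 0 in the other fits, and of replication genes 0 to 1 fell. The number of calls was 1098 in a fit of these 2 groups alone (541 of the 556 among them), 877 with DESeq2 and 182 at an adjusted p under 0.01. It was 1285 without LITAF library 1, 322 without LITAF library 3, 244 without LITAF library 4, and 272, 279, 244 and 365 without H/R libraries 1 to 4. Among the genes chosen by the naming rule, which were the ones followed, Zfp748-ps1, Ccne2, Chac1, Ftl1, Grn, Ccn2, Hmox1, Il18 and Col3a1 lost their call in at least 1 of these fits with a library left out, all with an unchanged sign.

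**Figure D2:**
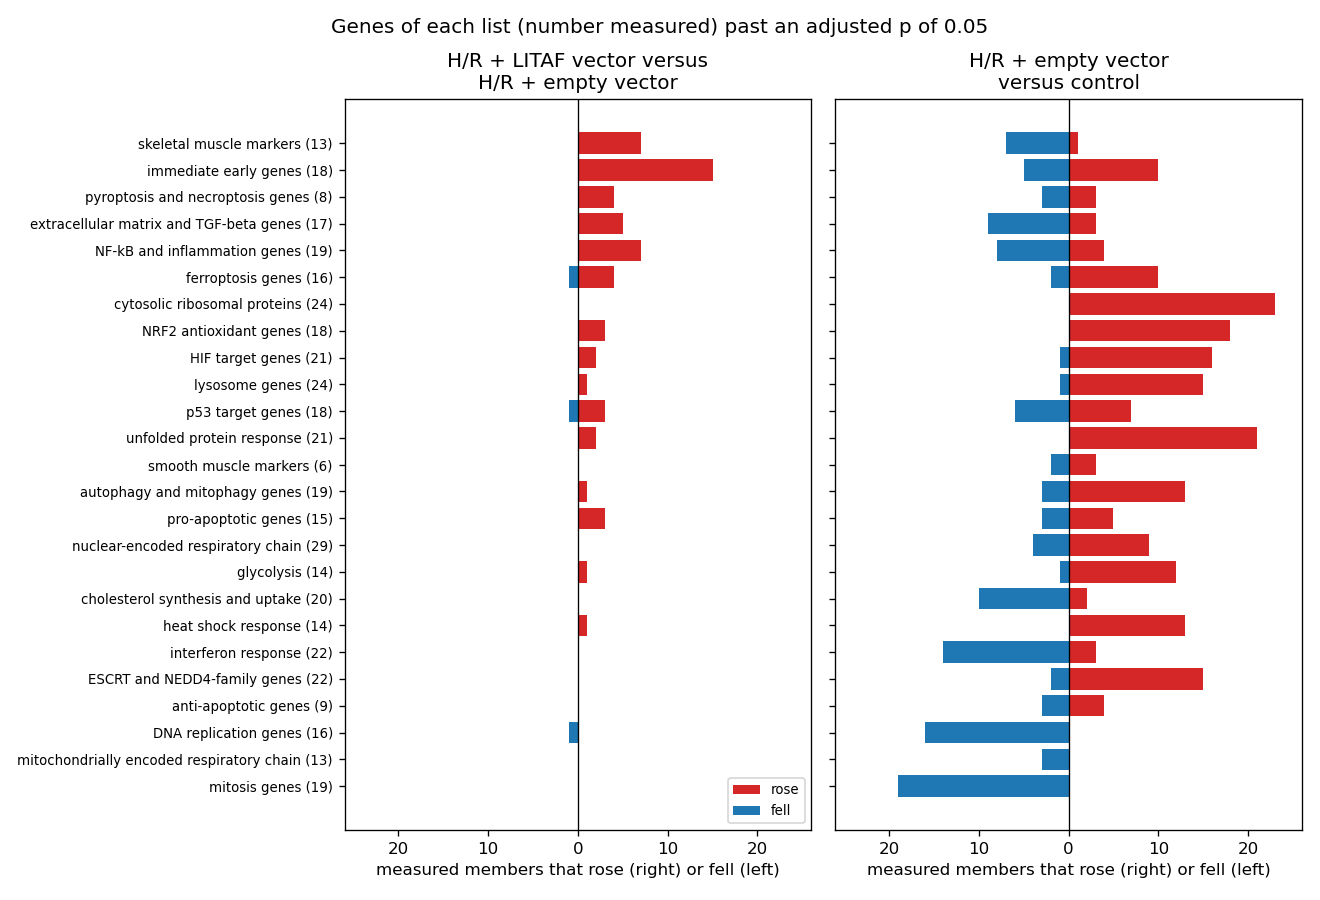
Number of genes in each tested list that rose (right, red) or fell (left, blue) at an adjusted p under 0.05, for the LITAF group against the H/R group (left panel) and the H/R group against control (right panel); the number measured is in brackets. With LITAF, 15 of 18 immediate early genes rose, while with H/R and the empty vector 21 of 21 unfolded protein response genes rose and 19 of 19 mitosis genes fell.

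The comparison of the H/R group with control describes the response to hypoxia, reoxygenation and the empty vector together. It also holds any difference in how the control values were made, which cannot be told apart from that response. Values that were not whole made up 2.79 to 3.34% in the control columns and 11.1 to 12.0% in the H/R columns. Fold changes and directions against control, here and below, carry this limit as well as their p-values. The largest rise was in the inducible heat shock protein gene Hspa1b, from 5.72 ± 0.639 to 732 ± 132 CPM (SD, n = 4), a 128-fold rise. Hspa5, the main chaperone of the endoplasmic reticulum, rose 16.4-fold, and Hmox1, which breaks down haem, rose 27.0-fold. Genes of cell division fell together, with the replication genes Rrm2 and Tyms 9.48-fold and 14.1-fold lower. The largest falls of single genes were in Mybph, Myog and Pln, the last a regulator of the sarcoplasmic calcium pump that went from 1120 ± 132 to 4.30 ± 0.903 CPM. Litaf stood at 473 ± 17.9 CPM in control and rose by log2 0.31 ± 0.10, adjusted p = 0.0145 by edgeR's quasi-likelihood test.

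The values of the control and H/R libraries are not independent of each other, which bears on every p-value against control. It can also reach LITAF against H/R, since the main fit took the spread from all 12 libraries. That comparison had 556 calls in the main fit and 1098 in the fit without control. Control and H/R libraries with the same number deviated together, with correlations across genes of 0.30 to 0.57, and H/R and LITAF libraries of the same number gave 0.05 to 0.20. In the 1314 genes with 1 to 10 mean counts in the H/R group, where counting noise is large, the same-number deviations of control followed those of H/R with a slope of 0.485 (95% bootstrap interval 0.447 to 0.524). The slope was -0.00931 for LITAF on H/R libraries. In 72 gene IDs the table held 2 rows with different control values and identical values in both H/R groups, with a median ratio of 1.17 between the rows for genes with at least 100 counts. These genes were left out. For LITAF against H/R, where their values are the same in both rows, a fit of the 2 groups with them kept, chosen after seeing the data, gave a fall in Ddit3 (log2 -0.37 ± 0.09, adjusted p = 0.0335 by edgeR's test) and a rise in Fosl1 (log2 0.57 ± 0.10, adjusted p = 0.00661).

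**Figure D3:**
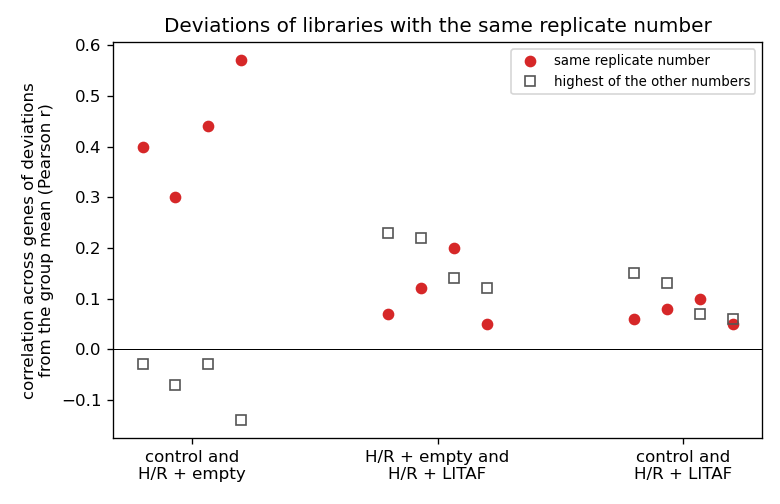
Pearson correlation across genes of each library's deviation from its group mean, for pairs of libraries with the same replicate number (red points) and the highest of the other numbers (open squares), for each pair of groups. Control and H/R libraries of the same number correlated at 0.30 to 0.57, above every other number.

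All 21 measured unfolded protein response genes rose, also when adjusted over the list alone. Creld2 rose 14.3-fold, Sdf2l1 10.1-fold and Dnajc3 7.69-fold. In the heat shock list 13 of 14 rose by both adjustments, with Hspb1 up 8.63-fold, Hsph1 6.09-fold and Bag3 4.76-fold, and Cryab did not pass (log2 0.05 ± 0.14). Hspa1l (21.4-fold) and Zfand2a (13.6-fold), outside the lists, were also among the largest rises. Hspa1l has a close paralog in Hspa1b. Ggct, of glutathione turnover, rose 16.1-fold, from 0.344 to 5.63 CPM. All 18 NRF2 antioxidant genes rose by both adjustments, with Nqo1 up 6.19-fold, Ftl1 5.31-fold and Osgin1 4.08-fold. These 3 lists passed the camera test (adjusted p = 7.78e-13, 2.48e-07 and 2.48e-07) and held with an estimated correlation.

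Of 21 HIF target genes 16 rose and 1 fell by both adjustments. Bnip3, a mitophagy receptor, rose 12.0-fold, the glucose transporter gene Slc2a1 6.92-fold, Vegfa 6.58-fold and Higd1a 6.46-fold. The list held with an estimated correlation (adjusted p = 0.00227). Of 14 glycolysis genes 12 rose and 1 fell by both adjustments, with Eno2 up 7.72-fold, Pdk1 6.78-fold, Pfkl 5.90-fold and Pgk1 3.91-fold. The gene that fell was Pfkm, the muscle phosphofructokinase (log2 -1.59 ± 0.15). The glycolysis call (adjusted p = 4.62e-06) was lost at adjusted p = 0.109 with an estimated correlation. Of 24 cytosolic ribosomal protein genes 23 rose by both adjustments, by log2 1.60 ± 0.11 for Rpl13 and 1.39 ± 0.11 for Rplp0; the call was lost at adjusted p = 0.161 with an estimated correlation.

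In the autophagy and mitophagy list 13 of 19 rose and 3 fell by both adjustments, with Sqstm1 up 4.12-fold, Gabarapl1 3.92-fold and Gabarap 2.69-fold (adjusted p = 0.0305 with an estimated correlation). Of 22 ESCRT and NEDD4-family genes, which sort membrane proteins for degradation, 15 rose and 2 fell by both adjustments, among the rises Wwp2 (2.53-fold) and Chmp2a (2.42-fold) (adjusted p = 0.0440 with an estimated correlation). Of 16 ferroptosis genes 10 rose and 2 fell by both adjustments, with Slc3a2 up 6.43-fold and Chac1 2.35-fold (adjusted p = 0.0495 with an estimated correlation). Of 24 lysosome genes 15 rose and 1 fell by both adjustments, with Tfeb up 2.93-fold, Atp6v0d1 2.15-fold and Ctsb 1.95-fold; this call was lost at adjusted p = 0.143 with an estimated correlation. In the fit of these 2 groups alone with an estimated correlation, the ESCRT, ferroptosis and autophagy calls were lost too (adjusted p = 0.138, 0.0608 and 0.0506), and 6 lists held: unfolded protein response, heat shock, NRF2, HIF, mitosis and DNA replication.

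All 19 mitosis genes and all 16 DNA replication genes fell by both adjustments. Ccna2 was 6.86-fold lower, Bub1b 6.58-fold, Ccnb1 4.13-fold and Tpx2 4.12-fold. Mcm6, of the replicative helicase, went from 3300 ± 260 to 550 ± 7.85 CPM, and Mcm5 was 4.59-fold lower. Both lists held with an estimated correlation (adjusted p = 0.00645 and 0.00204). Of 22 interferon response genes 14 fell by both adjustments, and 3 rose, or 4 when adjusted over the list alone. Ifit1 was 14.2-fold lower, Ifih1 3.47-fold and Parp14 2.88-fold, while the immunoproteasome gene Psmb8 rose 2.77-fold. Of 20 cholesterol genes 10 fell and 2 rose over all genes, and 13 and 2 adjusted over the list alone, with Acat2 2.52-fold and Dhcr7 2.02-fold lower. Of 17 extracellular matrix and TGF-beta genes 9 fell and 3 rose by both adjustments, with Col3a1 6.26-fold lower, Thbs1 4.50-fold, Col1a1 2.77-fold and Col1a2 2.53-fold. These 3 calls were lost with an estimated correlation, at adjusted p = 0.133, 0.286 and 0.324.

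Of 13 skeletal muscle markers 7 fell and 1 rose by both adjustments. Myog, a driver of muscle differentiation, went from 3870 ± 1920 to 14.1 ± 6.30 CPM, log2 -8.10 ± 0.58. Mybph was 377-fold lower, Myl4 3.53-fold and Myod1 2.93-fold, while Des rose 3.50-fold. The call was lost at adjusted p = 0.324 with an estimated correlation. Adora1, Igfbp5 and Pik3ap1 were 53.2-fold, 34.1-fold and 29.4-fold lower. C4b and Islr were 94.5-fold and 40.4-fold lower, with 1.61 and 0.556 CPM in control library 2 against at least 16.5 and 13.2 CPM in the other control libraries.

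In all, 3620 genes rose and 3628 fell, 7248 of 11398, with 1091 and 1474 by at least 2-fold; rises made up 49.9% of calls with TMM, 59.0% with library totals alone and 58.1% with upper-quartile scaling. CPM did not overlap for 6677 genes (58.6%). The 2.86% from chance holds for unpaired libraries, and so not for these groups, whose libraries are paired by number. Scaling by library totals moved the median log2 fold change of all genes from 0.01 to 0.13, so changes are stated relative to the TMM median. Of the 25 lists tested 16 passed camera, 10 up and 6 down, and 9 held with an estimated correlation. The cholesterol list no longer passed in the fit of these 2 groups alone (adjusted p = 0.0616), with library totals alone, with upper-quartile scaling, and without control library 2, control library 3 or H/R library 4.

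The LITAF group was also compared with control, which adds the effects of H/R, vector and LITAF. Hspa1b (167-fold), Hmox1 (39.2-fold) and Hspa1l (26.4-fold) rose most, and Pln (189-fold), Myog (121-fold) and Mybph (93.0-fold) fell most, with 4 of 4 libraries of each group apart. Litaf rose 4.95-fold, log2 2.31 ± 0.11. Of 18 immediate early genes 14 rose and 1 fell (adjusted p = 0.0209 with an estimated correlation), also adjusted over the list alone. In edgeR's test 3649 genes rose and 3717 fell. The limit on control values given above holds here too.

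A further question of the design is whether LITAF moved genes back toward control or further away. Of the 418 genes called in both comparisons, 269 had opposite signs and 149 the same sign. Egr1 fell with H/R (log2 -2.13 ± 0.11) and rose with LITAF (1.98 ± 0.11), to 980 ± 37.4 CPM against 1090 ± 143 in control. Fmod, Cilp, Igf2 and Trib1 also fell with H/R (log2 -2.45, -3.07, -2.84 and -1.52) and rose with LITAF (2.41, 1.40, 1.22 and 0.99). Srxn1, Casp8 and the phosphatase gene Dusp5 rose in both, by 5.44-fold and 3.44-fold, 1.97-fold and 3.98-fold, and 4.49-fold and 2.83-fold.

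Of the opposite signs, 228 genes fell with H/R and rose with LITAF, and 41 did the reverse; 105 genes rose in both and 44 fell in both. Independent lists of these sizes would give 135 and 42 genes of the opposite kinds (177 in all) and 135 and 42 of the same kinds (177 in all). The excess thus lies in genes that fell with H/R and rose with LITAF, and the other kinds were near or below their independent numbers. Both comparisons use the H/R libraries, which by itself gives fold changes a negative covariance. The observed correlation across genes was -0.10 and the covariance -0.0334. In 20 simulated sets of unchanged, independent groups the covariance was -0.0174, but control and H/R libraries here are paired by number, so that value is not the one for no change in these data. With the H/R libraries split 2 and 2 between the comparisons, in 6 assignments, 61 to 74 genes had opposite and 35 to 43 the same sign, with a covariance of -0.0324 to -0.0147. The 269 genes of opposite and 149 of the same sign became 486 and 308 with fits of 2 groups alone, 403 and 270 with the replicate block, 410 and 240 with DESeq2, and 45 and 18 at 2-fold or more in both. Without LITAF libraries 1 to 4 they became 516 and 414, 211 and 105, 150 and 101, and 129 and 72. Without H/R libraries 1 to 4 they became 139 and 72, 128 and 81, 123 and 71, and 175 and 99. The balance between the signs thus varied with the libraries used, and it was closest to even without LITAF library 1.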

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

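Of the tests weighed here, those of shared culture, of control values computed from H/R values, of mixed reads, and those of zinc finger genes for enrichment and on the axis of the LITAF libraries were chosen after the result was seen.

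Control and H/R libraries of the same number deviated together, which may come from the cultures or from how the values were made. A shared culture, day or batch can pass on true differences in expression but not counting noise. The same-number covariance exceeded the H/R variance beyond counting noise by 0.108 (95% bootstrap interval 0.0858 to 0.129). This cannot decide, since a shared culture can give it where true deviations are larger in control than in H/R. The control variance beyond counting noise was not computed in these 1314 genes, so a shared culture stays open. Reads of the H/R library mixed into the control library are argued against. The slope was 0.560 (0.355 to 0.740) in 31 genes at least 10 times higher in control, where so few reads cannot move the control count. Control values computed in part from the H/R values of the same number are a candidate explanation, but the slope below does not single them out. Reads of the control library mixed into the H/R library were not tested. In 20 genes with 1 to 10 counts in H/R and at least 50 in control, the covariance exceeded the H/R variance beyond counting noise by 0.0822. Its 95% bootstrap interval was -0.0306 to 0.179. The slope was 0.647 (0.364 to 0.879) in these 20 genes. In the 10 genes of the reverse kind it was 0.283 (0.0240 to 0.613), which cannot tell whether H/R values were computed from control. In the 72 repeated IDs the control values differed between rows, by a median of 1.17-fold at 100 counts or more, and the H/R values were identical. For those IDs this argues against H/R values computed from each row's control values, and it stays open for the other genes. In 204 genes with a decimal control value and at least 100 counts the same-number correlations were -0.07 to 0.08, against 0.37 to 0.59 in 8866 other genes, and no biological explanation other than a shared culture was tested.

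The axis that spread the LITAF libraries may be technical. Gene loadings on it correlated with gene length at a Spearman rho of -0.39 (permutation p = 0.0001, the smallest that 10000 permutations can give, over 11345 genes, which are not independent replicates). A bias that goes with gene length could give this. The length used is the span of the gene with its introns and not the length of the transcript, so RNA integrity was not tested by it. The fold change of LITAF against H/R correlated with gene length at 0.05 over all genes, but the called genes differed in median length, 30.4 kb for those that rose, 17.9 kb for those that fell and 24.1 kb for the others. A biological difference in how far each culture responded to the vector stays open and was not tested, since RNA integrity values per library were not used here.

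Zinc finger genes, a group chosen after their values were seen, made up 38 of the 131 genes that fell with LITAF (29.0%) and 2.59% of the genes tested; 1 rose. The odds ratio of 17.5 describes this and cannot exclude chance, since the group was chosen for it and its genes are correlated. The fall goes in part with the axis of the LITAF libraries: the median difference from the H/R mean was -0.09, -0.23, -0.40 and -0.48 in libraries 1, 3, 4 and 2, the order of their axis scores (-0.68, -0.20, 0.25 and 0.63), and the median loading of these genes lay at percentile 23.1. The median gap of the 295 zinc finger genes to other genes was -0.30. It stayed at -0.24 (95% bootstrap interval -0.27 to -0.20) after a linear trend on that axis was removed. Noise in the loadings can leave part of a trend in place, and the interval treats correlated genes as independent. That axis as the whole cause is therefore not excluded. The axis within the H/R group cannot be told apart from the effect, since the fold changes had no trend on it (correlation 0.01) and removing it left the gap at -0.30, and an effect of LITAF stays open.

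In fits of the 2 groups alone, 1 of 35 splits of the 8 libraries, the real one, gave as many genes for H/R against control (7352, highest other 0), for LITAF against H/R (1098, highest other 0) and for LITAF against control (6656, highest other 0), by edgeR with adjustment. Control and H/R libraries are paired by number, and only 8 of the 35 splits part all pairs, too few for a share under 0.05; the other 7 gave 0 genes and at most 383 at an unadjusted p under 0.05, and the 27 that keep a pair together at most 848. At an unadjusted p under 0.05 the 3 real splits gave 7652, 3048 and 7154 genes and the others at most 848, 2363 and 1393. For the 2 comparisons that are not paired, no other split gave as many genes as the real one. A share of 1 in 35 is the smallest these splits can give, and mixed splits count the real difference as spread within a group. A difference between cultures was not tested by them. For the lists, 5 of 35 splits gave as many as the 15 lists of H/R against control (highest other 15), so chance cannot be excluded for that number, and 1 of 35 gave as many as the 13 of LITAF against H/R (highest other 12). Splits that exchange 1 library of each group keep part of the real difference.

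Among 315 groups of 4 CPM values of the genes reported here, 22 had a library far from the other 3, and chance gives about 1 in 20. In control library 2 these were Il18 at 8.17 CPM (others 1.24 to 1.44), C4b at 1.61 (16.5 to 18.7), Islr at 0.556 (13.2 to 15.5), Mcm5 at 1260 (1320 to 1330) and Srxn1 at 0.889 (1.34 to 1.40). In control library 4 they were Ccn1 at 385, Serpinb7 at 13.4 and Tnfaip3 at 27.1 CPM. In control library 1 they were Hmox1 at 55.3 and Pfkl at 27.0 CPM, and in control library 3 Chmp2a at 33.4 CPM. In the H/R group they were Fos at 47.5 and Pgk1 at 830 CPM in library 1, Hspa1l at 8.95 CPM in library 2, and Bhlhe40 at 135 and Hgs at 152 CPM in library 4. In LITAF library 1 they were Adora1 at 3.58, C4b at 0.796, Rrm2 at 225 and Tnni1 at 1.36 CPM. Parp14 at 12.5 CPM in LITAF library 2 and Pik3ap1 at 3.93 CPM in LITAF library 3 complete the set.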

How the results depend on the processing

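The 2 values of Litaf kept their direction and their side of the threshold in every alternative run, from 1.94 to 2.06 (LITAF against H/R) and from 0.28 to 0.34 (H/R against control) with each library left out. Leaving out each library gave 6768 to 7224 genes for H/R against control, 6854 to 7586 for LITAF against control, 244 to 1285 for LITAF against H/R, 123 to 516 with opposite signs, and 15 to 16 and 11 to 14 lists. Fits of the 2 groups alone gave 1098 genes for LITAF against H/R and 486 with opposite signs, and DESeq2 gave 877 and 410. An adjusted p under 0.01 gave 182 genes for LITAF against H/R. A 2-fold minimum gave 2565 (H/R against control), 132 (LITAF against H/R), 2740 (LITAF against control) and 45 (opposite signs), fewer by construction. The H/R libraries split between the comparisons gave a median of 63.5 with opposite signs, with fewer samples. Camera with an estimated correlation gave 9 and 7 lists.

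With the replicate block, LITAF against H/R gave 873 genes, though these groups share only a number (correlations 0.07, 0.12, 0.20 and 0.05, and 1 of 4 libraries best with its own number). The falls among these went from 131 to 299, and genes of opposite and the same sign from 269 and 149 to 403 and 270. Alternatives chosen after seeing the data gave 887 genes for LITAF against H/R (2 groups with the block), 1108 (2 groups, first row of each repeated ID kept) and 4469 (2 groups with the axis as a covariate, which was taken from the same residuals, so its p-values are too small). Only genes with a decimal control value gave 183 for H/R against control, of 452 tested; in the fit of all genes 196 of these 452 were called (43.4%), against 7052 of 10946 other genes (64.4%). Apart from the alternatives whose construction shows it, the cause was not tested. Over all alternatives, 50 values of genes chosen by the naming rule and 22 of lists lost their call and none changed sign.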

Other observations

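Several gene groups moved little or in both directions. With LITAF, 3 of 15 pro-apoptotic genes rose, Casp8 (3.98-fold), Bcl2l11 (1.75-fold) and Bax (1.43-fold), with the same 3 rises and 1 fall adjusted over the list alone, while none of 9 anti-apoptotic genes passed. Of 18 p53 target genes 3 rose, among them Btg2 (2.39-fold) and Plk3 (1.71-fold), and Ccng1 fell (log2 -0.69 ± 0.16); Cdkn1a stood at log2 0.04 ± 0.13. Dnajb1 was the only 1 of 14 heat shock genes to rise (1.89-fold), Hk2 the only 1 of 14 glycolysis genes (1.44-fold), and Ulk1 the only 1 of 19 autophagy genes (1.48-fold). Of 21 unfolded protein response genes 2 rose, Chac1 (1.34-fold) and Asns (1.36-fold). With 1 library left out, 2 genes of this list rose without LITAF library 1, 1 without H/R library 4 and 0 in each of the other fits. Ddit3, a gene of this list left out for its repeated rows, fell in the fit that kept it (log2 -0.37 ± 0.09). None of 22 interferon, 22 ESCRT and NEDD4-family, 29 nuclear-encoded and 13 mitochondrially encoded respiratory chain, 20 cholesterol and 6 smooth muscle genes passed edgeR's test in the main fit. Without LITAF library 1, 3 mitochondrially encoded and 3 heat shock genes fell, 1 ESCRT and NEDD4-family gene rose and 2 fell, and 1 interferon gene rose and 1 fell. None of the lists in this paragraph passed the camera test in the main fit. The mitochondrially encoded list lay at an adjusted p of 0.0505. It passed with the replicate block (0.0244) and did not with an estimated correlation (0.694). The unfolded protein response list passed camera in the fit of the 2 groups alone (adjusted p = 0.0432).

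With H/R and the empty vector, 10 of 18 immediate early genes rose, Atf3 by 5.87-fold, and 5 fell, so the list did not pass (adjusted p = 0.136). In the NF-kB list 4 rose, among them Il6 (2.89-fold), and 8 fell, among them Vcam1 (log2 -2.40 ± 0.20) and Cx3cl1 (log2 -4.03 ± 0.43). In the pyroptosis and necroptosis list 3 rose and 3 fell, with Casp4 up 8.06-fold. Pro-apoptotic (5 up, 3 down), anti-apoptotic (4 and 3), p53 target (7 and 6) and nuclear-encoded respiratory chain genes (9 and 4) went both ways, 3 of 13 mitochondrially encoded genes fell, and 3 of 6 smooth muscle markers rose and 2 fell. In the anti-apoptotic, p53 and smooth muscle lists the median and the mean had different signs. Of the markers of cell types, 3 cardiomyocyte, 1 endothelial, 2 macrophage and leukocyte and 1 epithelial marker passed the count filter, too few to test as lists. The cardiomyocyte markers were Gata4, Nkx2-5 and Tnnt2, and Tnnt2 fell with H/R (log2 -2.16 ± 0.23) and rose with LITAF (log2 1.32 ± 0.23).

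In 11 genes 1 control library stood at 0 while each other control library had at least 20 counts, and in 8 of these the H/R library of the same number was at 0 too. Mylk2 had 356 to 507 counts in the other control libraries and at most 3 in the H/R group, and Unc45b 445 to 983 and at most 10; both were at 0 in library 4 of both groups. These genes were chosen after their values were seen.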
